A study of Rattus norvegicus with 6 samples.

How the data were processed

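Messenger RNA was sequenced from cultures of rat bone marrow stromal cells (BMSCs), the adherent cells of the marrow that can give rise to bone, fat and cartilage cells. Per the labels, primary cells were grown in alpha-MEM with 10% fetal bovine serum, and 3 samples were held for 7 days in an atmosphere of 1% O2. The other 3 samples were kept in normal culture, for which the labels give no oxygen percentage. Libraries came from a stranded poly(A) mRNA kit, per the labels' protocols. The extraction protocol in the labels speaks of muscle samples, whereas the source name, cell type and growth protocol all give BMSCs. The cell type could not be checked from marker genes, for the reason given below.

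The deposited table holds raw read counts per Ensembl gene ID, made by the authors. Per the submitters' processing notes, HISAT2 and featureCounts were used with the rat build rn6, and DESeq2 is named as well. Their versions, the annotation release and the strand setting are not given in the sources used here. Overlapping and antisense genes may therefore share reads. Library names in the labels matched the table's columns 1 to 1, and 0 columns belonged to other samples. All 32883 rows name a gene ID, and 13283 of them had 0 counts in all 6 libraries. The table does not pair IDs with gene names. The RefSeq gene table used as a reference lists 47357 genes and gives an Ensembl ID for 0 of them, so 0 of the IDs could be named. Gene symbols, coordinates, GC content and gene length were therefore not used here.

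Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 12702 genes. The 6898 removed genes that had any reads held between 0.088% and 0.101% of each library. Libraries were scaled by TMM factors, and 1% O2 was compared with control by the two-sided quasi-likelihood F-test. The fit had 1 term for the group and 4 residual degrees of freedom. The test also shares information on spread across genes, so its p-values rest on more than these 4 degrees of freedom. p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05 and no minimum fold. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. This approximation can be too small for large changes, and can lie below counting error where a group has few reads. CPM values, read counts scaled to a common library size with the TMM factors, were computed here from the deposited counts. Shares of reads were taken from the unscaled counts over each library's total. For principal components, log2 CPM had a prior count of 2.

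The design was fixed before the data were examined. It held a rule for named genes and 34 gene lists (hypoxia-inducible genes, glycolysis, the SP factors, bone, fat and cartilage genes, markers of other cell types and others). Because the IDs could not be named, the 34 lists and the parts of the rule that need a symbol were not run. What remained of the rule took, among genes past the threshold, those with an average log2 CPM of at least 1 and no overlap between the CPM of both groups, ranked by log2 fold change. The first 10 in each direction are summarised, and the first 2 in each direction are given in full by their IDs.

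The labels do not say whether the samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries were compared by a mean chi-square per gene over genes with at least 20 reads in the pair. This mean is 1 if only sampling noise separates them, with an SD of about 0.013. The replicate numbers 1 to 3 occur in both groups. Nothing in the labels states that they mark shared animals or batches, so the numbers were not taken to pair the samples. The correlations between the deviations of same-numbered libraries from their group means were -0.04, -0.05 and 0.01. For differently numbered libraries they lay between -0.014 and 0.051. With 3 libraries per group, such correlations can neither show nor exclude pairing.

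The fit was tested on simulated data for the comparison of 1% O2 with control. Its 12702 genes were drawn from the real means and library sizes and the fitted dispersion trend, and 200 of them were changed. Scatter of genes around that trend was not simulated. edgeR recovered 44% of 50 genes changed 1.2-fold, 72% of 50 changed 1.5-fold, 90% of 50 changed 2-fold and 100% of 50 changed 4-fold. It called 5 of 12502 unchanged genes. With 5718 genes called in the real data, the adjusted threshold is less strict there than in the simulation. These rates therefore do not carry over to the real data. Alternatives were median-of-ratios factors, library totals alone, 2 other low-count filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust dispersion estimates, a replicate block, other thresholds, thinning to equal depth and leaving out each library. The thinning and the counts of 2-fold changes per setting were added after seeing the data.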

Results

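Gene expression was measured by mRNA sequencing in primary rat BMSCs held at 1% O2 for 7 days and in cells kept in normal culture, with 3 libraries in each group. The control libraries held 13284507, 13273781 and 13361629 reads assigned to genes. The 1% O2 libraries were deeper, with 18533675, 14966785 and 14879124. At least 1 read was found for 16551 to 16723 genes per control library and for 16773 to 16910 genes per 1% O2 library. At this depth the median standard error of a log2 fold change was 0.09 over the 12702 tested genes. It was 0.23 among the 3175 least abundant and 0.05 among the 3176 most abundant.

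The libraries separated by group. The labels do not say whether the groups also differed in culture or preparation batch, and such a difference could not be told apart from oxygen. The first principal component of log2 CPM held 71.6% of the variance and placed the 3 control libraries at -25.3, -30.4 and -24.7 and the 3 libraries at 1% O2 at 24.97, 26.3 and 29.2. The second component held 9.8% and set Control replicate 2, at -19.1, apart from the other controls at 11.5 and 9.5. Libraries of different groups had a mean chi-square per gene between 40.6 and 52.2, where sampling noise alone gives 1. Within the 1% O2 group this value was 1.76 to 2.23. It was 1.51 between Control replicates 1 and 3, but 6.48 and 6.57 between Control replicate 2 and these. No pair agreed within sampling noise, so none was taken as repeat sequencing of another, and each library was counted as 1 sample. This does not show that they came from separate cultures. The biological coefficient of variation over all genes was 5.05%.

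**Figure D1:**
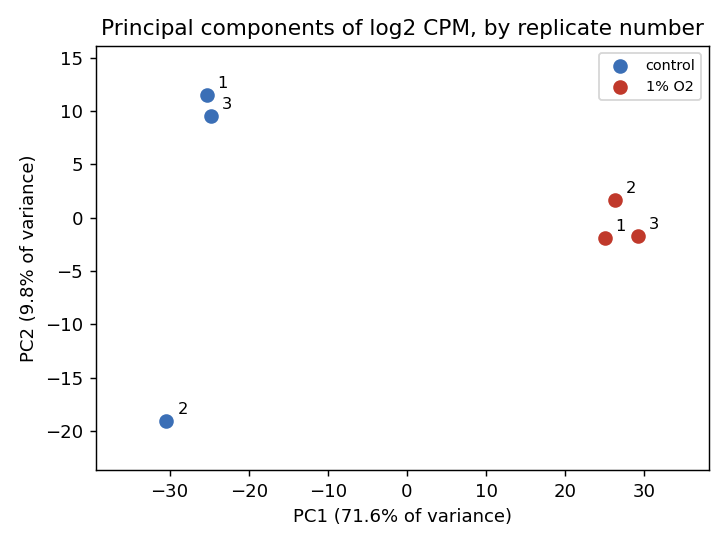
Principal components 1 and 2 of log2 CPM (arbitrary units) over 12702 genes. Each point is 1 library with its replicate number, and colour gives the group. The groups lie on opposite sides of the first component (71.6% of variance), and Control replicate 2 lies apart on the second (9.8%).

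The comparison of 1% O2 with control addresses how the transcriptome of these cells differs after 7 days of low oxygen. Of the 12702 tested genes, 5718 (45.0%) differed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3). Of these, 2932 genes were higher at 1% O2 and 2786 were lower. Most differences were small. The median log2 fold change was 0.42 among the higher genes, which is 1.34-fold, and -0.36 among the lower genes, which is 1.29-fold. The CPM of both groups did not overlap for 55.5% of all tested genes, where chance gives 10% for 3 libraries against 3. Among the changed genes the share was 97.95%, but these were chosen on the same libraries, so a high share follows. The near-even split was much the same with median-of-ratios factors, under which 51.1% of 5724 changed genes were higher, but not without scaling factors. TMM and median-of-ratios factors both centre the fold changes on no change, with median log2 fold changes of 0.0025 and 0.0018. Their agreement is therefore not independent evidence of an even split. With library totals alone, which lowers the log2 fold changes by a median of 0.09, 34.3% of the 6071 changed genes were higher in place of 51.3%.

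Larger changes were fewer. At least 1.5-fold differences were found for 916 higher and 695 lower genes, and at least 2-fold differences for 360 higher and 239 lower genes. The 2-fold counts were 358 higher and 240 lower with median-of-ratios factors. With library totals alone they were 297 and 309, without an excess of rises. At least 4-fold, 72 genes were higher and 30 lower, and with library totals 67 and 32. At least 8-fold, 23 genes were higher and 3 lower.

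**Figure D2:**
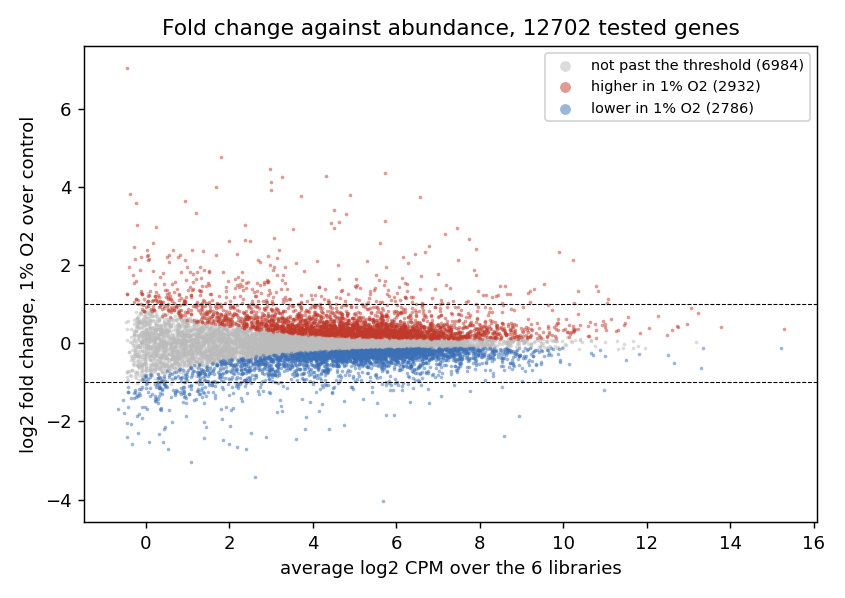
Log2 fold change of 1% O2 over control against the average log2 CPM of the 6 libraries, 1 point per tested gene; colour marks an adjusted p under 0.05 and its direction, and dashed lines mark 2-fold. The 2932 higher and 2786 lower genes lie mostly within 2-fold. The topmost point is a gene with 0 reads in every control library, so its fitted fold change depends on the prior count and is not a bound.

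Changed genes were found at all levels of expression. Among the 3176 most abundant genes (average log2 CPM of at least 5.82), 997 were higher and 963 lower, which is 61.7% of them, with a median size of change of 0.29 on the log2 scale. Only 72 of these were at least 2-fold higher and 23 at least 2-fold lower. Among the 3175 least abundant genes (average log2 CPM up to 2.66), 445 were higher and 437 lower, which is 27.8% of them, and 175 and 166 of these passed 2-fold. The median size of change among called genes was 0.88 there. The test detects only larger changes at low counts, so these shares do not show that low-abundance genes changed less often.

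The genes that were higher at 1% O2 took 34.4% ± 0.6 of all reads in control libraries and 44.6% ± 0.2 at 1% O2 (SD, n = 3 each). The genes that were lower took 32.9% ± 0.5 and 24.6% ± 0.2. These genes were chosen on the same libraries, so the shares describe the size of the shift and are not independent evidence of it. The 10 genes with the largest gains made up 29.9% of the reads gained by the higher genes, and the 100 with the largest gains made up 64.9%. Losses were spread more widely, with 25.8% and 47.3% for the 10 and 100 largest. These are unscaled shares, in which a gain by some genes lowers all others. Genes not past the threshold also fell, from a mean of 32.7% in controls to 30.7% at 1% O2. Part of the wider spread of losses may therefore come from the measure. The genes at least 2-fold higher went from 1.57% ± 0.02 to 3.91% ± 0.06 of reads, and those at least 2-fold lower went from 0.95% ± 0.03 to 0.352% ± 0.016. The 10 most abundant genes of each library held 15.1% ± 0.2 of reads in controls and 16.0% ± 0.1 at 1% O2. The groups did not overlap in this measure, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 samples against 3 allow.

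The deposited table does not pair gene IDs with names, so genes are identified by Ensembl ID alone. The largest rise under the fixed rule was that of ENSRNOG00000012892, from 0.219 ± 0.073 CPM in controls to 6.19 ± 0.88 CPM at 1% O2 (SD, n = 3 each). Its log2 fold change was 4.76 ± 0.29 (SE), or 27.1-fold, with an adjusted p of 1.32e-08 by edgeR. The control libraries held only 3, 4 and 2 reads of it, against 96, 89 and 102 at 1% O2. Counting error therefore limits the fold and is larger than this SE. Leaving out 1 library gave log2 fold changes of 4.54 to 5.01. ENSRNOG00000017766 followed, from 0.632 ± 0.113 to 14.2 ± 1.1 CPM, with a log2 fold change of 4.47 ± 0.18 and an adjusted p of 1.61e-10 by edgeR. Its control libraries held 10, 7 and 9 reads, so its SE also lies below counting error. Under this rule, which asks for an average log2 CPM of at least 1, the 10 genes with the largest rises had log2 fold changes of 3.77 to 4.76, and their mean CPM at 1% O2 lay between 5.56 and 99.6.

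The largest fall under the same rule was that of ENSRNOG00000021201, from 98.4 ± 4.3 CPM in controls to 5.94 ± 1.94 CPM at 1% O2. Its log2 fold change was -4.03 ± 0.13 (SE), which is 16.3-fold lower, with an adjusted p of 1.55e-11 by edgeR. Its values at 1% O2 were 7.46, 6.60 and 3.76 CPM, a spread that this SE understates. Leaving out 1 library gave log2 fold changes of -4.24 to -3.80. ENSRNOG00000002167 fell from 11.5 ± 0.2 to 1.05 ± 0.25 CPM, with a log2 fold change of -3.42 ± 0.16 and an adjusted p of 1.16e-09 by edgeR. The 1% O2 libraries held only 22, 17 and 11 reads of it, so its SE lies below counting error. The 10 genes with the largest falls under this rule had log2 fold changes of -4.03 to -2.40, and their mean CPM in controls lay between 3.72 and 98.4.

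**Figure D3:**
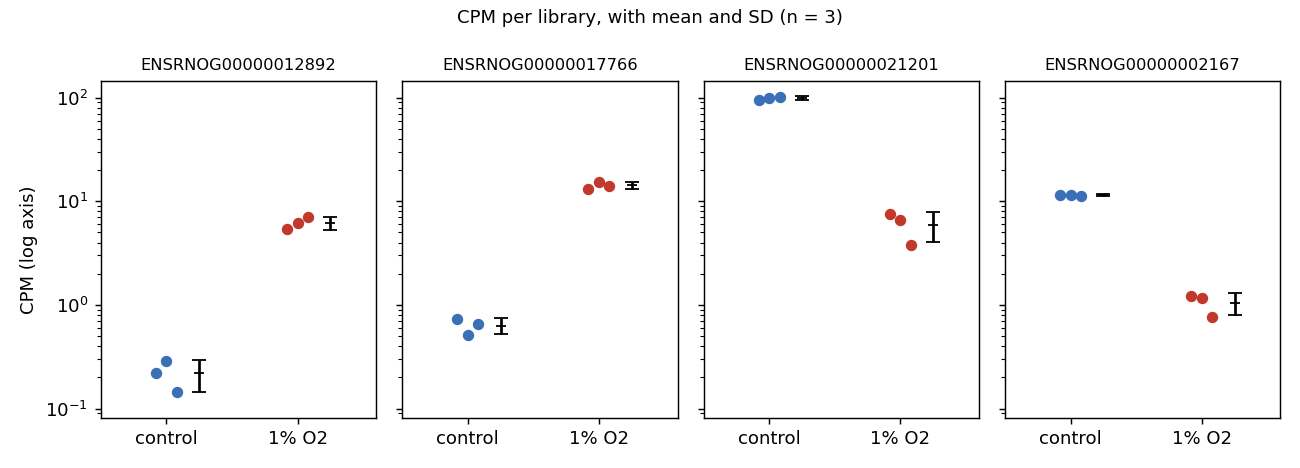
CPM per library on a log axis for the 2 genes with the largest rises and the 2 with the largest falls under the fixed rule; points are libraries, and bars give the mean and SD of 3. For each gene all 3 libraries at 1% O2 lie on the same side of all 3 controls, with ENSRNOG00000021201 falling from 98.4 to 5.94 CPM.

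The series title names the transcription factor SP1. The level of its transcript, and those of hypoxia-inducible, bone and other marker genes, were not analysed here because the IDs could not be named.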

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

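The numbers of changed genes (5718), higher genes (2932) and lower genes (2786) stayed within 1.5 times under 16 of 17 alternatives, at 3981 to 6071, 2080 to 3123 and 1901 to 3987. The exception was a minimum log2 fold change of 1, by construction, with 599 changed, 360 higher and 239 lower. Those 2-fold counts ranged from 297 to 471 and from 209 to 330 over 16 alternatives, all added after seeing the data. Of the 5718 genes, DESeq2 also called 4577 and limma-voom 5658, all in the same direction. Leaving out 1 library gave 4626 changed genes (without Hypoxia replicate 3) to 6017 (without Control replicate 2, of which 5275 were shared). The replicate block gave 5295 changed genes. Same-numbered libraries correlated at 0.01 at most and differently numbered ones at up to 0.051, which can neither show nor exclude pairing. The labels state no pairing, so the numbers were not treated as pairs. Library totals in place of TMM kept 4870 of the 5718 calls. The 4 genes given by ID kept their direction and call under all 15 settings. They were chosen as the largest changes in these same libraries, so this was likely beforehand. Other splits of the 6 libraries into 3 and 3 gave 0 changed genes by edgeR, hence 0 higher, lower or 2-fold changed, against 5718 for the real split, and at most 211 against 6637 at an unadjusted p under 0.05. The real split was 1 of 10, too few for a share under 0.05. Each other split also places libraries of both groups on each side. The oxygen difference then counts as spread, so few calls follow by construction. The contrast with the real split is therefore no measure of chance. The settings chosen beforehand for the gene lists were not run, since IDs could not be named. At the real depth and sample number, with spread from the fitted dispersion trend alone, 44% of simulated 1.2-fold changes were recovered. This rate does not carry over to the real data, and the part due to depth was not tested.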

Other observations

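The tests in this part were chosen only after the result, or a closely related value, was seen, except that leaving out each library was set before the data were examined. Apart from the oxygen contrast, the strongest structure among the libraries was in Control replicate 2. Among 5041 genes with an average log2 CPM of at least 5, 278 lay more than 0.3 log2 units below the mean of the other controls in this library, and 21 lay as far above. Between Control replicates 1 and 3 the same limits took 6 and 7 genes. Without Control replicate 2 the comparison called 6017 genes in place of 5718.

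Technical explanations for this library were examined. Lower depth is argued against, since the total of Control replicate 2 was only 0.37% below the mean of the other controls, while its mean chi-square per gene against them was 6.48 and 6.57, against 1.51 between those. RNA of the 1% O2 cells mixed into Control replicate 2 would raise the genes at least 8-fold higher at 1% O2. This was checked in 2 comparisons on 20 and 22 such genes, picked on a control library left out of the comparison. The median differences were -0.18 and -0.11 log2 units (bootstrap 95% upper limits -0.004 and 0.05). The bootstrap resampled genes, so its limits hold no spread between libraries, and both comparisons share Control replicate 2. The medians argue against an admixture that clearly raised these genes. A small rise could still be hidden by the other low values of this library. A small admixture in Control replicates 1 and 3 instead could give negative medians, and -0.18 and -0.11 lie between the limits set for and against it, so its presence stays open. As the cause for most of the 278 low genes it is argued against. Only 116 genes above the median abundance were at least 2-fold higher at 1% O2. An admixture that moves 8-fold induced genes this little could not lift genes below 2-fold by 0.3 log2 units. A GC, length or RNA-integrity bias also stays open, since no GC content or length was at hand. Deviations of Control replicate 2 from the other controls were weakly correlated along the table's order of tested genes. The rank correlation was 0.067 for adjacent tested genes and 0.038 for those 10 apart. The same values were 0.028 and 0.024 for Control replicate 1, and 0.032 and 0.003 for Control replicate 3. Those deviations are also taken against Control replicate 2. No biological explanation was tested, since the labels give none for a single control.

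Rises exceeded falls more as the fold grew, with 72 against 30 genes at 4-fold. At 2-fold the excess (360 against 239, ratio 1.51) depends on the scaling. Library totals, which lower the log2 fold changes by a median of 0.09, gave a ratio of 0.96. Median-of-ratios factors gave 1.49, but they centre the fold changes as TMM does. Which scaling is right was not tested, so the excess may be a matter of scaling. At 4-fold the lowest ratio under the other 2 scalings was 2.09, so the choice among these scalings does not account for the excess. They differ by a median of only 0.09 log2 units, and a larger shift between the groups was not tried. Scaling in general therefore stays open. Deeper 1% O2 libraries are argued against by the ratio of 2.37 after thinning to equal depth, and noise near the count floor by the ratio of 7.67 (23 against 3) among genes above the median abundance. That strong responses to 1% O2 are mostly inductions remains a hypothesis found and tested on the same 6 libraries.

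Tested genes that follow one another in the deposited table tended to move together. Rows were counted over the 12702 tested genes alone, so 1 row is the step to the next tested gene. The rank correlation of their log2 fold changes, across genes, was 0.130 at a distance of 1 row, 0.048 at 5 rows, 0.020 at 10 rows and 0.006 at 50 rows. A permutation test that shuffled the rows gave p = 1e-04 at 1 row, the smallest that 10000 arrangements can give, though genes are not independent replicates. The bias of Control replicate 2 is argued against as the whole cause, since fold changes taken against Control replicates 1 and 3 alone still had a correlation of 0.111 at 1 row, above the highest value of 0.032 when the rows of these fold changes were shuffled. Reads shared by overlapping genes stay open, above all for the excess at 1 row over 2 rows (0.130 against 0.075). The mean of 0.035 over distances 3 to 10, against at most 0.011 in shuffled rows, does not decide this without coordinates. If the rows follow genomic order, which could not be checked without coordinates, a shared response of chromosomal neighbourhoods or of gene families in tandem is a candidate explanation for the 0.130. It cannot be told apart from shared reads or from biases that follow the genome.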
